A study of Homo sapiens with 6 samples.

How the data were processed

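The series holds 6 RNA-seq libraries of the C42 prostate cancer cell line, 3 with a control shRNA (shCTR) and 3 with an shRNA against NSD2 (shNSD2). Per the labels' protocols, cells grew in RPMI medium with serum, total RNA was taken with a Qiagen kit, and libraries were made with a KAPA mRNA kit, which selects polyadenylated RNA. The deposited table gives raw read counts per gene, by Ensembl gene identifier and symbol, with no normalization, judged from whole numbers that sum to different totals in each library. Per the submitters' processing notes, the authors used CASAVA 1.8.2, STAR 2.6.0a and the GRCh38 genome. The counting program, annotation release, strand setting and any filter on rows are not given in the sources used here. Without a stated strand setting, reads of overlapping and antisense genes cannot be told apart, and reads of near-identical copies may be split among them. The table has 31413 genes, of which 12 have a count of 0 in all 6 libraries and 0 are mitochondrially encoded.

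Coordinates, gene types, exon lengths and GC content came from GENCODE 29 on GRCh38, in which 31313 of the gene identifiers were found and 100 were not. Exon length was counted over all annotated exons of a gene merged, so it can exceed the length of the transcript expressed. Gene symbols are those of the table, so some are older names.

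Groups were taken from the sample titles. Counts were tested with edgeR 4.0.16 in R 4.3.3, with its filterByExpr filter by group, TMM normalization and the quasi-likelihood test (glmQLFit and glmQLFTest), without a covariate. The filter left 17160 genes and removed 14253. P-values were adjusted by the Benjamini-Hochberg method over all genes tested, and genes with an adjusted p under 0.05 were called changed. The common biological coefficient of variation was 0.106. Standard errors were derived from the log2 fold change and the F statistic. CPM values are scaled by TMM, and means are given with the SD over 3 libraries. NSD2 was also compared with an exact two-sided permutation test of its CPM values.

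In total 32 gene lists (8 primary and 24 secondary) were written from general knowledge before the data were examined, and 703 of their 785 entries were matched to a row. They cover histone methylation, MHC class I and class II presentation, type I interferon, interferon gamma, chemokines and cytokines, NF-kB, checkpoint and NK ligands, androgen receptor targets, luminal, basal, neuroendocrine and mesenchymal genes, mitosis, DNA replication, MYC, p53, hypoxia and glycolysis, oxidative phosphorylation, cholesterol, fatty acids, unfolded protein and integrated stress response, heat shock, immediate early genes, TGF-beta, Wnt, cancer-testis antigens, leukocyte markers, fibroblast and endothelial markers, mitochondrially encoded transcripts, histones and ribosomal proteins. Entries with no row or below the low-count filter were not tested, so nothing is said here of their change. The 29 lists with at least 5 tested members were tested with camera of limma 3.58.1, a competitive test with a preset correlation between genes of 0.01, adjusted over the lists. Of its 7 calls at an adjusted p under 0.05, 0 held with an estimated correlation. The fry test of whether a list moves on balance in 1 direction called 5 lists, which were DNA replication, TGF-beta, mitosis, NF-kB and neuroendocrine.

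Genes named in the text were chosen by a rule fixed before the data were examined. It takes NSD2. It takes the 6 higher and 6 lower protein-coding genes of largest absolute log2 fold change among called genes with a mean of at least 5 CPM and no overlap of CPM between groups. From each primary list it takes the 3 called members of smallest p, from each secondary list 1, and 2 more where camera called the secondary list. For a primary list without a called member it would take the 2 of highest CPM, which did not occur. This gave 66 genes. Other genes in the text were chosen after their values were seen, and some genes are not reported here.

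Alternatives fixed before the data were examined were DESeq2 size factors, upper-quartile factors and plain library size in the edgeR fit, the DESeq2 1.42.0 Wald test, limma-voom, no low-count filter, a filter of at least 1 CPM in 3 libraries, a fold threshold, robust dispersion, the replicate number as a block, each library left out in turn, and camera with an estimated correlation. A correction that removes each library's smooth trend of log2 CPM on GC content and log exon length was added after the data were seen.

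The fit was tested on simulated data. Counts were drawn for 17160 genes at the real means and library sizes, with 200 genes changed, and 16874 genes were in the fit. It recovered 48% of the 100 genes changed 1.5-fold and 77% of the 100 changed 2-fold. Of its 133 calls, 8 were false, and 0 of 30 unchanged lists were called. Far more genes, 5263, were called in the real data, so an adjusted p under 0.05 meant a stricter unadjusted p in the simulation. The recovery and the share of false calls therefore do not carry over to the real data. The simulated genes were drawn independently and the lists at random, so this does not measure false calls of the real lists. Members of those can move together, with an estimated correlation of 0.971 for ribosomal proteins. No pair of libraries within a group agreed within sampling noise, since chi-square per degree of freedom ran from 4.09 to 42.8. Figures were drawn with matplotlib 3.10.9 in Python 3.11.15.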

Results

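RNA was sequenced from C42 cells, a human prostate cancer line commonly written C4-2 and derived from LNCaP, that carried a control shRNA (shCTR) or an shRNA against NSD2 (shNSD2). NSD2, also named WHSC1, is a histone methyltransferase that places dimethylation on lysine 36 of histone H3. The series asks, by its title, how NSD2 bears on immune infiltration in prostate cancer. Each group held 3 libraries, numbered 1, 2 and 4 for shCTR and 1, 2 and 3 for shNSD2. Total counts ran from 19412896 to 20665494 per library, between 27364 and 27990 genes had a count, and the 10 most abundant genes took 4.21% to 4.73% of the counts. A floor of 3 counts was 0.145 to 0.155 CPM, the unit of counts scaled to the library total, which covers counting error only. The labels do not say whether the libraries came from separate cultures, so the p-values measure the spread between these libraries, which may be technical.

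NSD2 transcript fell in the shNSD2 libraries to 40.7% of its level in the controls. Its level was 214.0 ± 12.1 CPM in shCTR and 87.1 ± 2.28 CPM in shNSD2 (SD, n = 3 each), a log2 fold change of -1.30 (SE 0.0870, edgeR quasi-likelihood test, adjusted p = 8.03e-05). The control libraries held 219, 223 and 200 CPM and the knockdown libraries 85.3, 86.4 and 89.7 CPM. NSD2 (ENSG00000109685) lies on chromosome 4 of GRCh38 from 1871424 to 1982207. An exact two-sided permutation test of the CPM values gave p = 0.1, the smallest that 3 against 3 libraries allow.

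Lower NSD2 came with changed transcript levels of 5263 of 17160 genes tested, 2658 higher and 2605 lower at an adjusted p under 0.05. Of these, 414 were higher and 571 lower by at least 2-fold. IGFBP3, a secreted protein that binds insulin-like growth factors, fell 14.6-fold, from 337 ± 98.5 to 23.1 ± 16.6 CPM (SD, n = 3; edgeR adjusted p = 0.00171). FN1, which encodes the matrix protein fibronectin, fell 8.41-fold from 6354 ± 2406 to 755 ± 257 CPM (adjusted p = 4.75e-04). The calcium-binding protein gene S100P rose 4.63-fold from 31.03 ± 16.3 to 144 ± 6.74 CPM (adjusted p = 0.00126).

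Among the other protein-coding genes with a mean of at least 5 CPM and no overlap between groups, the largest falls were in GCG, the glucagon precursor (log2 fold change -3.75), the lipoprotein lipase gene LPL (-3.26), BRINP1 (-3.26) and the secreted semaphorin gene SEMA3C (-3.19). GCG went from 15.2 ± 10.6 to 1.12 ± 0.389 CPM (SD, n = 3; edgeR adjusted p = 0.00191), with 26.1 CPM in shCTR 1, and the log2 fold change of GCG was -3.12 without shCTR 1. The largest rises beside S100P were in UGT2B11, an enzyme gene of steroid glucuronidation (1.93), RASD1 (1.90), MGLL, which encodes monoacylglycerol lipase (1.82), the carnitine acetyltransferase gene CRAT (1.79) and the phosphodiesterase gene PDE2A (1.76). MGLL went from 28.8 ± 3.32 to 102 ± 10.5 CPM (SD, n = 3; edgeR adjusted p = 6.86e-05). UGT2B11 is nearly identical to other UGT2B genes, so its reads may be split among them. On GRCh38, IGFBP3 lies on chromosome 7 from 45912245 to 45921874, FN1 on chromosome 2 from 215360440 to 215436172, S100P on chromosome 4 from 6693069 to 6697170, and MGLL on chromosome 3 from 127689062 to 128052190.

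The number of changed genes varied with the library left out. Leaving out a library makes its group smaller and lowers the power. A fall in calls in such a fit, here and for the lists below, therefore need not mark that library. Only the rise without shCTR 4 runs against the loss of power. It was 3225 without shCTR 1, 2633 without shCTR 2, 8262 without shCTR 4, 2986 without shNSD2 1, 3042 without shNSD2 2 and 2436 without shNSD2 3. Across 11218 genes with a mean of at least 5 CPM, shCTR 4 lay 0.49 of the way from the mean of the other controls to the mean of the knockdown libraries, against -0.44 for shCTR 1 and 0.00 for shCTR 2. For most gene groups, the level in shCTR 4 is given below as a percentage of the mean log2 shift of the shNSD2 libraries from shCTR 1 and 2. For NSD2 itself that value was 10.6%. The percentage does not show the spread between shCTR 1 and 2, which for some lists was near the size of the shift.

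**Figure D1:**
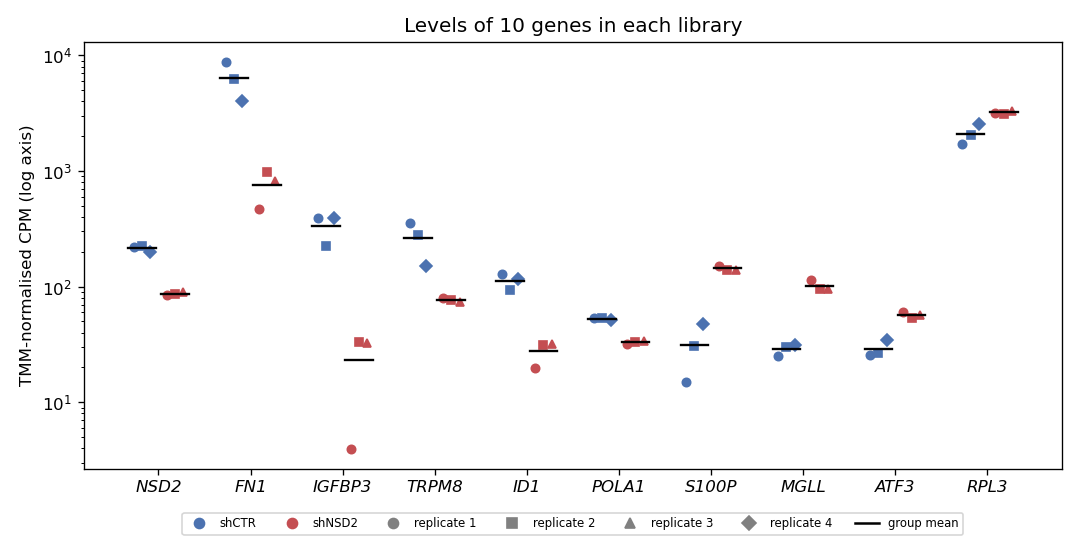
CPM of 10 genes (log axis) in each of the 3 shCTR libraries (blue) and 3 shNSD2 libraries (red), with marker shapes for the replicate numbers and black bars for the group means. NSD2 lies at 200 to 223 CPM in the control libraries and at 85.3 to 89.7 CPM in the knockdown libraries, while shCTR 4 (diamond) is the control nearest to the knockdown libraries for FN1, TRPM8, S100P and RPL3.

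Genes of TGF-beta and SMAD signalling were lower, with 10 of 16 tested members falling and 1 rising, also when adjusted over the list alone. ID1, a transcriptional inhibitor induced by BMP and TGF-beta signals, fell 4.06-fold from 113 ± 18.0 to 27.7 ± 7.01 CPM (SD, n = 3; edgeR adjusted p = 2.34e-04). The related gene ID3 fell by 1.16 on the log2 scale, and the inhibitory SMAD gene SMAD6 fell by 1.31. TGFBR2, the type II receptor of TGF-beta, fell from 2.48 ± 1.06 CPM to 0.15 ± 0.0461 CPM, which is at the floor, so the size of its fall is loosely set (SD, n = 3; edgeR adjusted p = 6.16e-04). ID2 fell by 1.57 on the log2 scale (both chosen after the values were seen). The list median was -0.88, with a camera adjusted p = 2.68e-10, and adjusted p = 0.603 with an estimated correlation. Between 9 and 11 members were lower whichever library was left out, the 1 rise was lost without shNSD2 3, and shCTR 4 stood at 22.1% of the shift.

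Among mesenchymal genes, 6 of 13 tested members fell and 2 rose, with the same counts adjusted over the list alone. Beside FN1, the adhesive glycoprotein gene THBS1 fell 6.27-fold from 588 ± 304 to 93.7 ± 30.1 CPM, and LOX, which encodes the collagen cross-linking enzyme lysyl oxidase, fell 2.85-fold (SD, n = 3; edgeR adjusted p = 0.00117 and 5.36e-04). The collagen genes COL1A1 (0.52) and COL5A1 (0.88) were the 2 that rose, named after their values were seen. The list median was -0.42, with a camera adjusted p = 0.0424 and adjusted p = 0.839 with an estimated correlation. The camera call was also lost without shCTR 1 (adjusted p = 0.056) and without shCTR 2 (adjusted p = 0.0766), within a leave-one-out range of 0.00275 to 0.0766. shCTR 4 stood at 62.9% of the shift, and 4 to 8 members were lower with a library left out. Of 7 tested fibroblast and endothelial markers, 2 rose and 2 fell, the same adjusted over the list alone (camera adjusted p = 0.779), and 1 rose and 1 fell without shCTR 1, shCTR 2, shNSD2 1 or shNSD2 2. COL3A1, a fibrillar collagen gene near the floor, fell from 1.20 ± 0.214 to 0.253 ± 0.0928 CPM (SD, n = 3; edgeR adjusted p = 0.00217), and this list shares COL1A1 with the mesenchymal one.

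DNA replication genes fell together: 30 of 35 tested members were lower, 32 when adjusted over the list alone. POLA1, the catalytic subunit of DNA polymerase alpha, fell from 52.8 ± 0.873 to 33.1 ± 0.879 CPM, GINS1 of the replicative helicase from 84.0 ± 1.48 to 54.7 ± 1.37 CPM, and the S-phase transcription factor gene E2F1 from 98.5 ± 7.29 to 60.4 ± 4.04 CPM (SD, n = 3). Their edgeR adjusted p-values were 6.62e-04, 9.08e-04 and 0.00110. All 35 members had a negative log2 fold change, with a median of -0.54 (camera adjusted p = 2.61e-18, and adjusted p = 0.603 with an estimated correlation). Between 24 and 31 members were lower whichever library was left out. shCTR 4 stood at -6.07% of the shift.

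Of 30 tested mitotic genes, 14 fell and 1 rose, and 18 fell when adjusted over the list alone. ANLN, a cytokinesis scaffold, fell by 0.61 on the log2 scale, the proliferation marker MKI67 by 0.99 and the spindle checkpoint kinase gene BUB1B by 0.39 (edgeR adjusted p = 0.00171, 0.00334 and 0.00606). The list median was -0.25 (camera adjusted p = 7.50e-04, and adjusted p = 0.672 with an estimated correlation), and shCTR 4 stood at -47.7% of the shift. Lower members numbered 5 without shCTR 2, 6 without shNSD2 1, 5 without shNSD2 2 and 6 without shNSD2 3, and the 1 rise was lost in the 5 fits that kept shCTR 4, while 2 rose without it. Of 16 tested replication-dependent histone genes, 4 fell and 1 rose, the same adjusted over the list alone (camera adjusted p = 0.450). The linker histone gene HIST1H1B fell by 2.07 on the log2 scale, from 2.47 ± 1.34 to 0.584 ± 0.111 CPM (SD, n = 3), with 0.990 CPM in shCTR 4. shCTR 4 stood at 89.8% of the histone list's shift. Reads of histone genes may be shared among copies, and 1 to 5 histone genes were lower with a library left out. The rise among them was lost without shCTR 2, shNSD2 2 or shNSD2 3.

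Targets of p53 held 8 higher and 2 lower members among 25 tested, the same adjusted over the list alone, with a median of 0.04 (camera adjusted p = 0.250). FDXR, which encodes ferredoxin reductase, rose from 24.7 ± 2.84 to 39.8 ± 0.380 CPM (SD, n = 3; edgeR adjusted p = 0.00165). CDKN1A, the p21 cell cycle inhibitor (0.54), and the secreted stress factor gene GDF15 (1.44) were among the members that rose, both named after their values were seen. shCTR 4 stood at -57.6% of the shift of this list, and 6 to 8 members were higher and 1 to 6 lower with a library left out. MYC targets showed 1 higher and 6 lower of 30 tested, the same adjusted over the list alone (camera adjusted p = 0.732). CAD, the enzyme that starts pyrimidine synthesis, fell by 0.70 on the log2 scale (edgeR adjusted p = 0.00407), and the MYC list had 10 higher members without shCTR 4, its 1 rise being lost in the other 5 fits. Its lower members numbered 2 without shCTR 2, shNSD2 2 or shNSD2 3 and 3 without shNSD2 1.

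In the machinery of H3K36 and H3K27 methylation, 7 of 22 tested genes fell and 1 rose, also when adjusted over the list alone. MSH6, a mismatch repair protein that reads H3K36 trimethylation, fell from 72.7 ± 4.74 to 42.4 ± 3.63 CPM (SD, n = 3). The maintenance DNA methyltransferase gene DNMT1 fell by 0.54 on the log2 scale and EZH2, the H3K27 methyltransferase, by 0.40 (edgeR adjusted p = 7.54e-04 for MSH6, 0.00302 for DNMT1 and 0.00641 for EZH2). The list as a whole did not pass the test (median -0.18, camera adjusted p = 0.0980), and shCTR 4 stood at 68.9% of its shift. Lower members numbered 11 without shCTR 4, 3 without shCTR 2 or shNSD2 3, and 4 without any other library. The 1 rise was lost in the 5 fits that kept shCTR 4, and 3 members were higher without shCTR 4. After the correction for GC content and gene length, added after the data were seen, 5 members were higher and 3 lower (median -0.04), so the balance of the counts turned.

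**Figure D2:**
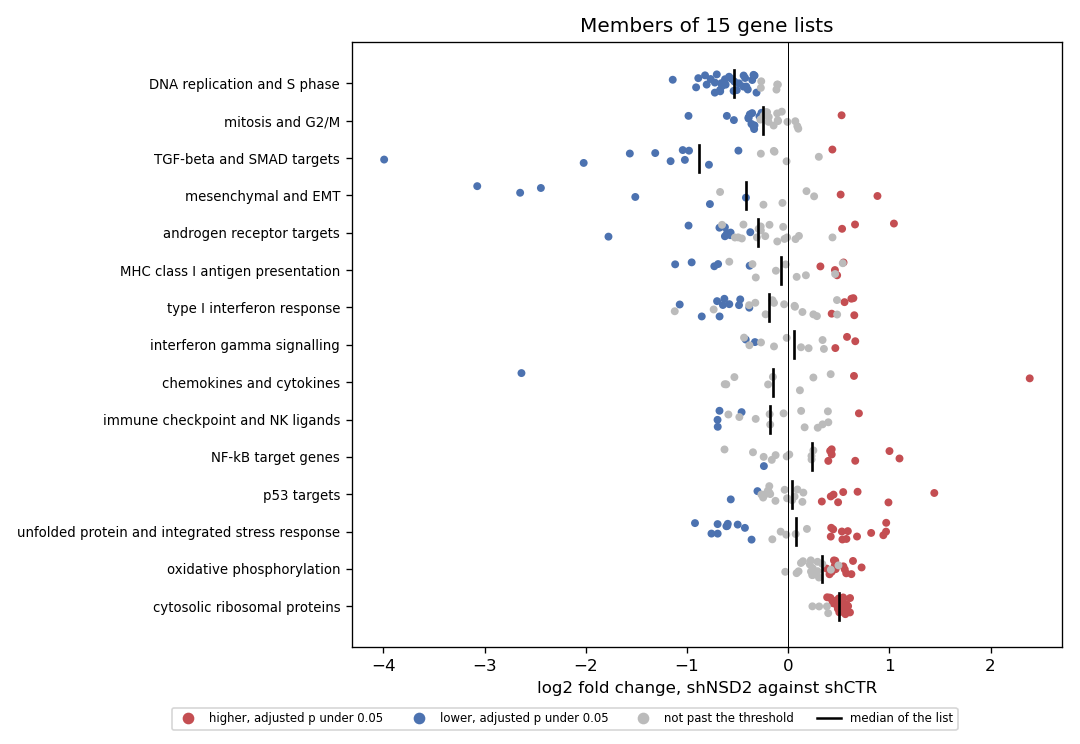
Log2 fold change of each tested member of 15 gene lists, shNSD2 against shCTR, with red points higher and blue points lower at an adjusted p under 0.05, grey points not past the threshold and black bars at list medians. Medians run from -0.88 for TGF-beta and SMAD targets to 0.50 for cytosolic ribosomal proteins.

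Genes of MHC class I antigen presentation changed in both directions, 4 of 18 tested members (22 listed) rising and 5 falling, the same adjusted over the list alone. PSMB8 and PSMB9 were below the filter, with at most 8 and 5 counts in a library. ERAP1, an aminopeptidase that trims peptides in the endoplasmic reticulum, fell 2.17-fold from 26.7 ± 5.81 to 12.3 ± 1.41 CPM (SD, n = 3; edgeR adjusted p = 0.00141). PDIA3, a disulphide isomerase of the peptide-loading complex, fell from 1169 ± 72.3 to 704 ± 24.8 CPM, and the chaperone gene CANX fell from 1437 ± 256 to 889 ± 73.1 CPM (SD, n = 3; edgeR adjusted p = 0.00175 and 0.00710). Among the members that rose were HLA-B (0.48), HLA-E (0.46) and the proteasome activator gene PSME1 (0.55), chosen after the values were seen. HLA genes are highly similar, so reads may be split among them. The list did not pass the test (median -0.07, camera adjusted p = 0.537), and shCTR 4 stood at 118% of its shift. With a library left out, 2 to 4 members were higher and 3 to 7 lower. Of 12 listed members of MHC class II presentation, 3 were tested. Of these, HLA-DMA rose from 3.02 ± 0.205 to 4.66 ± 0.767 CPM (SD, n = 3; edgeR adjusted p = 0.0224), also adjusted over the list alone, a call lost in 4 of the 6 fits without a library.

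Type I interferon response genes were split as well, 5 of 30 tested members (42 listed) higher and 10 lower, or 5 and 11 adjusted over the list alone. OAS3, a sensor of double-stranded RNA, fell from 35.0 ± 1.94 to 22.4 ± 2.19 CPM, whereas the ubiquitin-like modifier gene ISG15 rose from 19.2 ± 1.97 to 28.2 ± 1.91 CPM and the exonuclease gene ISG20 from 12.1 ± 2.01 to 18.7 ± 1.30 CPM (SD, n = 3). Their edgeR adjusted p-values were 0.00209, 0.00449 and 0.00665. MX1, an antiviral GTPase gene (-0.85), was also lower and IFITM2 (0.65) higher, both chosen after the values were seen, and IFITM genes share similar sequence. The list did not pass the test (median -0.19, camera adjusted p = 0.433), and shCTR 4 stood at 30.9% of its shift. Lower members numbered 3 without shCTR 2, 4 without shNSD2 3, 5 without shCTR 1 and 6 without shNSD2 1 or shNSD2 2, and higher ones 7 without shCTR 4 and 3 in each other fit.

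Of 26 listed genes of interferon gamma signalling, 14 were tested. Of these, 3 rose and 2 fell, the same adjusted over the list alone (median 0.06, camera adjusted p = 0.784). CXCL10 and CXCL11 were below the filter, with at most 5 and 2 counts in a library, and CXCL9 had no row. The receptor subunit gene IFNGR2 rose from 5.99 ± 0.720 to 8.96 ± 0.250 CPM and the guanylate-binding protein gene GBP2 from 2.37 ± 0.0635 to 3.75 ± 0.193 CPM (SD, n = 3; edgeR adjusted p = 0.00990 and 0.0141). WARS, the tryptophanyl-tRNA synthetase gene, rose by 0.47 on the log2 scale (edgeR adjusted p = 0.0218). The receptor subunit gene IFNGR1 (-0.33) and the kinase gene JAK1 (-0.42) were the 2 that fell, named after their values were seen. shCTR 4 stood at 98.2% of the list's shift, and with a library left out 1 to 4 members were higher. Lower members numbered 3 without shCTR 4 and 0 by edgeR in the other 5 fits, where 2 or 3 fell at an unadjusted p under 0.05. The call of WARS was lost in the 5 fits without a library other than shCTR 4, and that of GBP2 without shCTR 2, shNSD2 2 or shNSD2 3. Of 28 listed leukocyte markers, 4 were tested (CD8A, NKG7, CSF1R and CORO1A), and 0 of them were called by edgeR, DESeq2 or limma-voom over all genes. Adjusted over the list alone, 1 was higher and 1 lower, and 2 had an unadjusted p under 0.05. Where a library was left out 5 or 6 markers were tested, and 1 was called higher by edgeR without shCTR 4 and 1 without shNSD2 2.

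Of 40 listed chemokine and cytokine genes, 27 had a row and 11 were tested. Of these, 2 rose and 1 fell, the same adjusted over the list alone (camera adjusted p = 0.925). CCL2 and CXCL8 were below the filter, with at most 7 and 4 counts in a library, and CCL5 and CX3CL1 had no row. Most of the list was therefore not measured, which is not the same as unchanged. TGFB2, a TGF-beta ligand, fell 6.22-fold from 12.9 ± 3.64 to 2.08 ± 1.15 CPM (SD, n = 3; edgeR adjusted p = 9.86e-04). The cytokine gene IL32 rose 5.23-fold from 0.586 ± 0.264 to 3.07 ± 0.651 CPM, and the angiogenic factor gene VEGFA rose 1.57-fold from 193 ± 34.7 to 302 ± 31.5 CPM (SD, n = 3; edgeR adjusted p = 0.00106 and 0.00731). The mean of this list was negative while camera gave the direction up, and shCTR 4 stood at 113% of the list's mean shift. Without shCTR 4, 3 members were higher and 2 lower.

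Targets of NF-kB held 7 higher and 1 lower of 18 tested members, or 8 and 3 adjusted over the list alone. NFKB2, a precursor subunit of the alternative NF-kB pathway, rose from 51.7 ± 6.42 to 81.8 ± 4.33 CPM (SD, n = 3; edgeR adjusted p = 0.00204). The A20-binding protein gene TNIP1 (0.43) and the apoptosis inhibitor gene BIRC3 (1.10), chosen after their values were seen, also rose. The list did not pass camera (median 0.23, adjusted p = 0.130) but its members moved up on balance by fry (adjusted p = 0.0171). With an estimated correlation the camera adjusted p was 0.672, and the median was 0.06 after the GC and length correction, which was added after the data were seen. shCTR 4 stood at -18.9% of the shift. Higher members numbered 4 without shCTR 1, shCTR 2 or shNSD2 1, and 3 without shNSD2 3. The 1 fall was lost in the 5 fits that kept shCTR 4, and 3 members were lower without shCTR 4.

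Of 17 tested immune checkpoint genes and NK ligands (28 listed), 4 fell and 1 rose, the same adjusted over the list alone (median -0.18, camera adjusted p = 0.431). CD47, the signal that inhibits phagocytosis, fell 1.62-fold from 65.7 ± 5.65 to 40.5 ± 3.22 CPM, and the B7 family gene CD276 fell 1.62-fold from 228 ± 40.7 to 141 ± 6.66 CPM (SD, n = 3; edgeR adjusted p = 0.00141 and 0.00403). PVR, a ligand of TIGIT and DNAM-1, fell from 106 ± 13.1 to 76.8 ± 4.25 CPM (SD, n = 3; edgeR adjusted p = 0.00917). The costimulatory ligand gene TNFSF4 (-0.68) was the other that fell and the NKG2D ligand gene ULBP2 (0.70) the member that rose, both named after their values were seen. Lower members numbered 3 or 4 whichever library was left out, the rise was lost without shCTR 2 or shNSD2 1, 2 members were higher without shCTR 4, and shCTR 4 stood at 45.0% of the list's shift.

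Among 30 tested androgen receptor targets, 9 fell and 3 rose, or 11 and 4 adjusted over the list alone. TRPM8, a cation channel of prostate epithelium, fell 3.42-fold from 262 ± 104 to 76.5 ± 3.27 CPM (SD, n = 3; edgeR adjusted p = 0.00136). The stress-response gene NDRG1 fell by 0.60 on the log2 scale and the zinc finger gene ZBTB10 by 0.63 (edgeR adjusted p = 0.00559 and 0.00574). The list median was -0.30 (camera adjusted p = 0.0150, adjusted p = 0.839 with an estimated correlation, and fry adjusted p = 0.150), and shCTR 4 stood at 80.4% of the shift. The camera call was lost without shCTR 2 (adjusted p = 0.0632) and without shNSD2 1 (adjusted p = 0.0645), within a leave-one-out range of 1.51e-04 to 0.0645, and the lower members numbered 18 without shCTR 4 and 5 without shCTR 2 (6 without shNSD2 1). Higher members numbered 1 without shCTR 2 or shNSD2 2, 4 without shCTR 4 and 2 in the other fits.

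Luminal epithelial genes showed 3 higher and 5 lower of 15 tested, or 3 and 6 adjusted over the list alone (camera adjusted p = 0.636). GATA2, a transcription factor of the luminal prostate, fell from 437 ± 16.6 to 288 ± 23.7 CPM (SD, n = 3; edgeR adjusted p = 0.00287). Of 8 tested basal genes, 3 fell and 1 rose, also adjusted over the list alone (camera adjusted p = 0.521). The growth factor receptor gene EGFR fell 2.48-fold from 350 ± 140 to 141 ± 16.7 CPM (SD, n = 3; edgeR adjusted p = 0.00484), and shCTR 4 stood at 136% of the basal list's shift and -29.7% of the luminal one. Of 23 listed neuroendocrine genes 5 were tested, of which 2 rose, 3 adjusted over the list alone (camera adjusted p = 0.131, fry adjusted p = 0.0235). The Notch ligand gene DLL3 rose from 11.9 ± 3.24 to 23.2 ± 0.948 CPM (SD, n = 3; edgeR adjusted p = 0.00291), and shCTR 4 stood at 35.4% of this list's shift. With a library left out, the luminal list had 1 to 4 higher and 1 to 6 lower members, and the basal list 2 to 3 lower, with its 1 rise lost in the 5 fits that kept shCTR 1. Higher neuroendocrine genes numbered 1 without shNSD2 2, 3 without shCTR 2 or shCTR 4, and 2 in the other fits.

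The unfolded protein and integrated stress response list was divided, with 12 of 27 tested members rising and 10 falling, the same adjusted over the list alone (camera adjusted p = 0.632). ATF3, a stress-induced transcription factor, rose 1.96-fold from 29.04 ± 4.84 to 56.8 ± 3.18 CPM (SD, n = 3; edgeR adjusted p = 7.54e-04). Split after the values were seen, the 13 genes of the integrated stress response held 12 that rose, and the 14 genes of chaperones and degradation in the endoplasmic reticulum held 10 that fell. Among the former were the amino acid enzyme gene ASNS (0.58) and the glutathione-degrading enzyme gene CHAC1 (0.94), and among the latter the chaperone genes HSPA5 (-0.70) and HYOU1 (-0.92). shCTR 4 stood at 55.5% of the shift of the former part and 26.4% of the latter. Higher members of the whole list numbered 6 without shNSD2 3 and 7 without shCTR 2.

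Of 13 tested heat shock genes, 4 fell and 1 rose, the same adjusted over the list alone (camera adjusted p = 0.573). HSPB1, a small heat shock protein gene, rose 1.81-fold from 798 ± 98.1 to 1447 ± 126 CPM (SD, n = 3; edgeR adjusted p = 0.00191). Immediate early genes held 6 higher and 2 lower of 21 tested, also adjusted over the list alone (camera adjusted p = 0.0811). ATF3 belongs to this list too, and the phosphatase gene DUSP4 (1.61) and the AP-1 subunit gene JUND (1.04) rose, both named after their values were seen. shCTR 4 stood at 29.1% of the shift of the immediate early genes, of which 4 to 6 were higher and 1 to 3 lower with a library left out, and 4 were higher and 4 lower after the GC and length correction. Relative to the mean of shCTR 1 and 2, the immediate early list stood at -0.16 in shCTR 1, 0.16 in shCTR 2 and 0.23 in the shNSD2 mean. With a library left out, 2 to 5 heat shock genes were lower, and 3 were higher without shCTR 4.

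Of 27 tested cytosolic ribosomal protein genes, 23 rose, 26 adjusted over the list alone. RPL3 rose from 2106 ± 417 to 3218 ± 88.0 CPM, RPL32 from 607 ± 139 to 915 ± 89.3 CPM and RPS19 from 289 ± 66.1 to 422 ± 29.6 CPM (SD, n = 3; edgeR adjusted p = 0.0154, 0.0190 and 0.0210). The list median was 0.50 (camera adjusted p = 7.74e-08, adjusted p = 0.839 with an estimated correlation, and fry adjusted p = 0.115). shCTR 4 stood at 71.1% of the shift, and reads of these genes may be shared with their processed pseudogenes. Higher members numbered 27 without shCTR 4, 5 without shCTR 1, 2 without shNSD2 2, 1 without shNSD2 1 and 0 by edgeR without shCTR 2 or shNSD2 3, where 21 and 20 had an unadjusted p under 0.05.

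Of 31 tested oxidative phosphorylation genes, 13 rose, 15 adjusted over the list alone, and 18 did not pass the test. NDUFV1 of complex I rose from 177 ± 23.5 to 242 ± 8.48 CPM, UQCRC1 of complex III from 215 ± 24.6 to 289 ± 9.10 CPM and COX5B of complex IV from 104 ± 29.6 to 160 ± 8.14 CPM (SD, n = 3; edgeR adjusted p = 0.0122, 0.0125 and 0.0176). The list median was 0.34 (camera adjusted p = 2.90e-05, adjusted p = 0.839 with an estimated correlation, and fry adjusted p = 0.125), and shCTR 4 stood at 82.8% of the shift. Higher members numbered 27 without shCTR 4, 6 without shNSD2 2, 5 without shCTR 1, 1 without shNSD2 1 or shNSD2 3, and 0 by edgeR without shCTR 2, where 12 had an unadjusted p under 0.05. The list of mitochondrially encoded transcripts had no row in the table and was not analysed here.

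Other metabolic lists had members in both directions. Hypoxia and glycolysis genes held 5 higher and 4 lower of 30 tested, or 6 and 4 adjusted over the list alone (camera adjusted p = 0.531), with VEGFA and NDRG1 among them, and shCTR 4 stood at 72.9% of the shift. Relative to the mean of shCTR 1 and 2, that list stood at -0.12 in shCTR 1, 0.12 in shCTR 2 and 0.13 in the shNSD2 mean. Cholesterol biosynthesis genes held 7 higher and 5 lower of 23, or 7 and 6 adjusted over the list alone (camera adjusted p = 0.450). STARD4, a sterol carrier gene, rose from 15.3 ± 1.70 to 24.6 ± 2.90 CPM (SD, n = 3; edgeR adjusted p = 0.00347). Fatty acid synthesis genes held 6 higher and 2 lower of 19, or 6 and 3 adjusted over the list alone (camera adjusted p = 0.578; the median was -0.13 and the mean 0.06). AGPAT2, an acyltransferase of phospholipid and triglyceride synthesis, rose from 16.6 ± 2.86 to 29.4 ± 0.386 CPM (SD, n = 3; edgeR adjusted p = 0.00171). Higher members with a library left out numbered 1 to 10 for hypoxia and glycolysis, 3 to 10 for cholesterol and 4 to 6 for fatty acids. Lower members numbered 3 to 5 for hypoxia and glycolysis and 2 to 6 for cholesterol. For fatty acids 5 were lower without shCTR 4, 1 without shCTR 1 or shNSD2 1, and 0 by edgeR without shCTR 2, shNSD2 2 or shNSD2 3, where 5, 4 and 3 fell at an unadjusted p under 0.05.

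Wnt targets had 2 higher and 4 lower of 13 tested members, or 3 and 4 adjusted over the list alone (camera adjusted p = 0.445). The transcription factor gene ASCL2 rose 2.35-fold from 2.83 ± 0.626 to 6.64 ± 0.377 CPM (SD, n = 3; edgeR adjusted p = 0.00178), while LEF1 (-1.50) and AXIN2 (-0.86) fell, both chosen after their values were seen. Of 12 tested cancer-testis antigen genes, 3 rose and 1 fell, the same adjusted over the list alone (camera adjusted p = 0.450). SAGE1, a member of that class, rose from 3.70 ± 0.887 to 6.37 ± 0.0909 CPM (SD, n = 3; edgeR adjusted p = 0.00970), and shCTR 4 stood at 51.5% of the shift of the Wnt list and 132% of that of the antigen list. Higher antigen genes numbered 1 without shCTR 2, shNSD2 1 or shNSD2 3, 2 without shCTR 1 and 4 without shCTR 4, and the 1 fall was lost in the 5 fits that kept shCTR 4. With a library left out, 1 to 3 Wnt targets were higher and 3 to 5 lower.

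**Figure D3:**
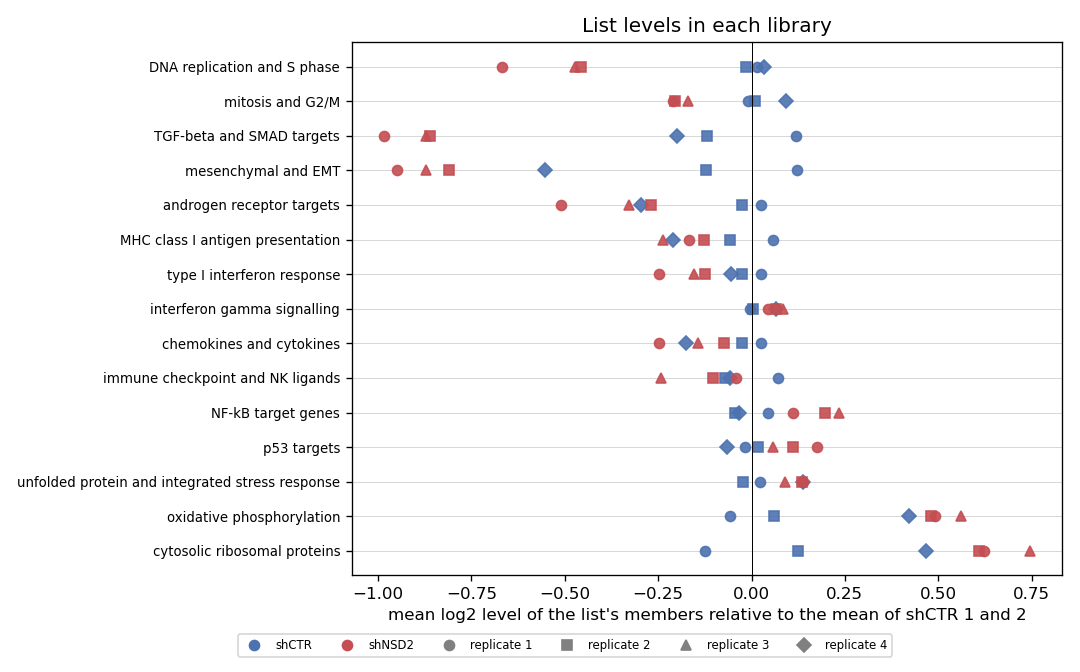
Mean log2 level of the tested members of 15 gene lists in each library, relative to the mean of shCTR 1 and 2, with shCTR in blue, shNSD2 in red and marker shapes for replicate numbers. shCTR 4 (blue diamond) lies beside the knockdown libraries for oxidative phosphorylation (82.8% of the shift) and with the other controls for DNA replication (-6.07%).

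Fold changes also went with gene length. Across 11205 genes, which are not independent replicates, log2 fold change and exon length had a Spearman's rho of -0.38, and log2 fold change and GC content a rho of 0.28. In the fifth of genes with the shortest exons the median log2 fold change was 0.24 and 34.9% of genes were higher, while in the fifth with the longest the median was -0.16 and 30.4% were lower. The slope of log2 level per doubling of length was 0.07 in shCTR 1, 0.03 in shCTR 2 and -0.09 in shCTR 4, against -0.11, -0.14 and -0.18 in the shNSD2 libraries. After a correction for both, added after the data were seen, 5237 genes were called, 3994 of them among the 5263. The corrected log2 fold change of ISG15 was 0.24 instead of 0.56, and NSD2 fell by 1.002. DNA replication then had 32 lower members, TGF-beta and SMAD targets 10 lower, ribosomal proteins 20 higher and oxidative phosphorylation 17 higher, while the NF-kB median went from 0.23 to 0.06. The balance of higher and lower members turned from 1 and 7 to 5 and 3 for H3K36 and H3K27 methylation. It evened out from 6 and 2 to 4 and 4 for immediate early genes, and from 12 and 10 to 10 and 10 for the stress response list.

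**Figure D4:**
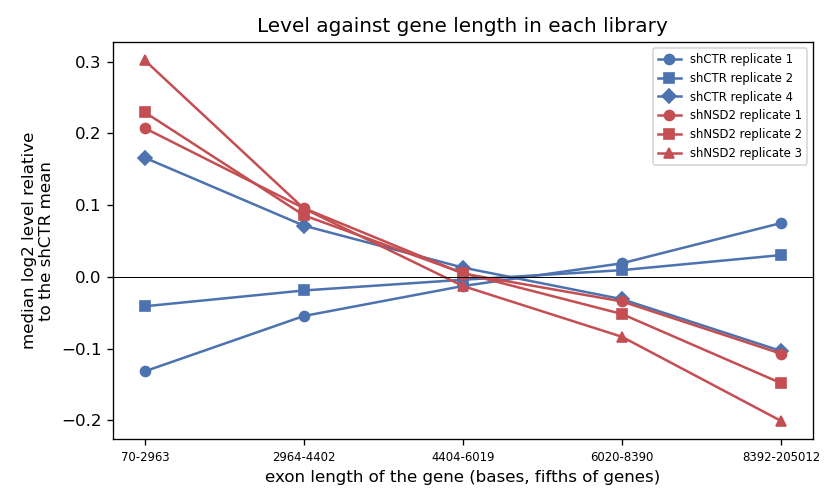
Median log2 level of genes relative to the shCTR mean, in 5 bins of genes ordered on exon length, for each of the 6 libraries (blue shCTR, red shNSD2). In the fifth of shortest genes the knockdown libraries lie at 0.21 to 0.30, shCTR 4 at 0.17, and shCTR 1 and 2 at -0.13 and -0.04.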

Additional observations from a re-analysis of the deposited data

How the results depend on the processing

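The correction for GC content and gene length was chosen after the data were seen. NSD2 was lower under each alternative run, by 1.27 to 1.34 on the log2 scale in the fits without a library and by 1.002 after that correction. The changed genes (5263) numbered 985 with a 2-fold threshold (414 higher, 571 lower), because fewer genes meet it, and 2436 to 8262 with a library left out (1116 to 4251 higher, 1320 to 4011 lower). The fewest were without shNSD2 3 and the most without shCTR 4. Each of these fits had a smaller group and so less power, which alone can end calls, while the count rose without shCTR 4. All other settings gave 4694 (DESeq2) to 6243 genes. That highest count came from the fit with the replicate number as a block, which rested on the libraries numbered 1 and 2 alone. There shCTR 4 and shNSD2 3 each had a block of their own, so they did not bear on the contrast. The block fit shared 4710 genes with the main calls. Only numbers 1 and 2 occur in both groups, and same-numbered libraries did not deviate together (r = 0.04 and -0.17 across genes), so the numbers were not read as pairs. Upper-quartile factors moved the split to 55.5% higher from 50.5%.

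With an estimated correlation the adjusted p was 0.839 for androgen receptor targets, mesenchymal genes, oxidative phosphorylation and ribosomal proteins, 0.672 for mitosis, and 0.603 for DNA replication and TGF-beta. By fry it was 0.150 for androgen receptor targets, 0.125 for oxidative phosphorylation, and 0.115 for mesenchymal genes and ribosomal proteins. With a library left out the camera adjusted p ran from 1.51e-04 to 0.0645 for androgen receptor targets and from 0.00275 to 0.0766 for mesenchymal genes, which also gave 0.0976 with the filter of 1 CPM. Without shCTR 2, 1 list that camera did not call in the main fit passed the threshold. The cause of these changes was not tested. Of 65 named genes beside NSD2, 9 lost their call in a fit without a library or with the block (HLA-DMA, GBP2, WARS, NDUFV1, UQCRC1, COX5B, RPL3, RPL32 and RPS19) and 25 changed at least 2-fold. Lists were tested again only with the estimated correlation, fry, DESeq2 size factors, the 1 CPM filter, the block, the GC and length correction and each library left out. No named gene changed direction, nor did a list test past the threshold in those settings. After the GC and length correction, however, the H3K36 and H3K27 list went from 1 higher and 7 lower members to 5 and 3.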

Other observations

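The grouping tests of fry calls and the comparison of control libraries along the knockdown axis were chosen after the results were seen, and so was the split of the stress list.

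Genes ranked next after the named ones add to the picture. Among those higher in shNSD2 were the metallothionein gene MT2A (log2 fold change 1.599), whose reads may be shared with related copies, and DDIT4, an inhibitor of mTOR signalling (1.402). Among those lower were the imprinted gene PEG10 (-2.87), the ephrin ligand gene EFNB2 (-2.50), the pseudokinase gene TRIB2 (-2.31) and ID4 (-2.40), which like ID1, ID2 and ID3 is an inhibitor of basic helix-loop-helix factors. EFNB2 fell from 128 ± 24.6 to 22.7 ± 3.63 CPM (SD, n = 3; edgeR adjusted p = 6.86e-05). Within 500 kb of NSD2, 4 of 17 tested neighbours were higher and 3 lower, among them TACC3 (-0.29) and FGFR3 (-0.37). On chromosome 19 the median log2 fold change was 0.16 over 808 genes, and 0.09 after the GC and length correction. After that correction every chromosome had a positive median, and chromosome 14 had a larger one, 0.11, so chromosome 19 no longer stood apart.

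The real grouping of the libraries called 5263 genes, and the other splits of 3 against 3 called 0 each by edgeR, with 67 to 1811 genes at an unadjusted p under 0.05 against 7512. In all, 1 of the 10 splits, the real one, reached that count, and 10 splits are too few for a share under 0.05. Camera called 7 lists in the real split and up to 9 in the others, with 7 of 10 splits reaching at least the real count, so the number of camera calls did not set the real grouping apart. Fry called 5 lists in the real split and at most 1 in the others, so that 1 of the 10 splits, the real one, reached its count, and 10 splits are again too few. Each other split put libraries of both groups on each side, which adds the difference between the groups to the spread within sides. Few edgeR or fry calls were therefore likely there whatever caused the real ones.

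Ribosomal protein and oxidative phosphorylation genes had a median log2 fold change of 0.45 in shNSD2 over 58 members. Whether a trend with gene length and GC content was the whole cause cannot be decided. The median after correction was 0.41 (95% bootstrap interval over the members 0.35 to 0.45). The members moved together, with an estimated correlation of 0.971 for ribosomal proteins and 0.787 for oxidative phosphorylation. The interval therefore leaves out the spread between libraries. Also, the exon length used was that of merged exons. That length had a median of 3717 bases for ribosomal proteins and 3236 for oxidative phosphorylation. It can exceed the length of the transcript expressed, so the correction may be partial. Library scaling stays open: the smallest median under the other scalings was 0.44, but these moved the median of all genes by at most 0.0224, too little to test it. Variation that also occurs among control libraries may account for much of the rise, since shCTR 4 showed 76.6% of the shift. The knockdown itself stays open, as untested.

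Members of the interferon and MHC class I lists went both ways, and shorter genes tended to be the higher ones (Spearman's rho of log2 fold change and length -0.33 over 61 members, -0.08 after correction). If the length and GC trend were the whole cause, a full correction would have ended most calls. The correction used merged exon length, which can exceed the transcript's, so it may be partial and the share of calls kept does not decide. After it, 82.8% (24 of 29) kept call and direction. Of these 24, 18 had a smaller log2 fold change after correction, with a median share of 0.84 left and the lowest, 0.44, in ISG15 (0.56 to 0.24), followed by EIF2AK2 (-0.49 to -0.24). Among the 5 that lost their call, JAK1 went from -0.42 (SE 0.135) to -0.32 (SE 0.125) and PARP9 from -0.38 (SE 0.102) to -0.20 (SE 0.0832), so the calls ended because the folds shrank. The trend may have contributed to those 5 and to the folds that became smaller. Its full share stays open, and so does an effect of the knockdown.

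shCTR 4 lay between the groups, at a position of 0.49. RNA of shNSD2 cells mixed into a library otherwise like shCTR 1 and 2 would need 1 fraction for all genes. The fraction needed was 0.30 for higher genes and 0.58 for lower ones, a difference of -0.284 (95% bootstrap interval over genes -0.341 to -0.228), and 0.156 for NSD2. This argues against mixing alone. But shCTR 1 and 2 also differed along the axis, at -0.44 and 0.00, so mixing together with such variation stays open. The trend with gene length and GC content stays open. The part of it that the correction removed moved the position only to 0.461. The correction used merged exon length, which can exceed the transcript's, so it may be partial and this does not decide. Variation among control libraries along the axis of the knockdown stays open: across 11218 genes, control differences correlated with the shift of shNSD2 from the remaining control (r = 0.761 for shCTR 4 minus 1, 0.629 for 4 minus 2 and 0.450 for 2 minus 1), but the positions of shCTR 1 and 4 already imply this, so it does not decide. No label gives a batch or day, and no biological explanation was tested.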
